A study of Mus musculus with 6 samples.

How the data were processed

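The samples were 3 pools of anterior cingulate cortex, each from 10 adult wild-type mice. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads from 50 µg of total RNA, fragmented with magnesium ions and enriched with an m6A antibody of Synaptic Systems. Stranded libraries of the enriched (IP) and unenriched (input) fragments were read as pairs of 150 bases on an Illumina NovaSeq. All 6 libraries contributed to the deposited tables, as 1 IP and 1 input library per list, and the lists were not pooled.

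Per the submitters' processing notes, the authors used fastp 0.19.4, HISAT2 2.0.4, StringTie 2.1.2, edgeR 4.1 and HOMER 4.10, with no role or order stated for any of them. The peak caller and its settings are not given in the sources used here. The notes name the human assembly GRCh38, but the gene coordinates in the tables match the mouse assembly GRCm38: of 18887 genes, 16649 had their name in the RefSeq table of that assembly, all of these were on the same chromosome, and 12288 (73.8%) had both ends within 1000 bp. In the authors' deposited tables each peak has a log2 enrichment of IP over input, per the legend deposited with them, and the values are never negative. The deposited p-value of each peak is under 0.05 in all lists, and an adjusted p-value by the Benjamini-Hochberg method stands beside it. A few deposited peaks, 30, 34 and 61 in the lists, had an adjusted p over 0.05 and were kept. The length of each peak in the deposited tables is a genomic span in bp that includes introns, with a median of 500, 525 and 537 bp. The annotated region, transcript type and gene of each peak are also the authors'. Starts are counted from 0 in the tables and were raised by 1 for printing.

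The tables hold no counts or values per library, so depth, its confidence intervals, expression and a comparison of IP with input libraries were not analysed here. Because enrichment is a ratio, a peak with few input reads can reach a high value, and its precision is not known from the tables. Peak values were used to describe, rank and filter within a list.

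Tables were analysed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1. A peak was called shared when it overlapped a peak on the same strand by at least 1 bp in both other lists. The count was set against 100 random placements of every peak of the other lists within its own gene, introns included, since no exon annotation was used here. For the agreement of enrichment, Spearman's and Pearson's correlations were taken across overlapping peaks of each pair of lists. Regions were described with the authors' annotation, with mean and SD over 3 replicates.

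The design, the 16 gene lists and a first set of alternative settings were fixed before the data were examined. The lists were actin turnover, postsynaptic density and glutamate receptors, presynaptic release, GABAergic transmission, m6A writers, erasers and readers, immediate early genes, stress and mood related signalling, chromatin and transcription regulators, ribosomal proteins, nuclear-encoded oxidative phosphorylation, glycolysis and housekeeping, and markers of excitatory neurons, astrocytes, the oligodendrocyte lineage, microglia, and endothelial and mural cells. They were chosen by hand from general knowledge, and 10 of their 548 genes are in a pair of lists. Of the 65 symbols for oxidative phosphorylation, 58 were in the gene table, since the list holds old and new symbols of some genes. Genes were named by a fixed rule: Cap1 and Ythdf1, the 15 genes with the highest peaks by their lowest enrichment over the 3 lists, the 5 with the most shared peaks, and the 3 members of each list with the highest shared peak by the same measure, with up to 3 members lacking any peak. Some genes that the rule names are not reported here. Genes named beyond this rule are marked in the text.

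The share of listed genes with a shared peak was compared with that of all other genes having a peak in at least 1 list by two-sided Fisher's exact test. Matching on exonic length had been planned where an annotation of exons allowed it. For enrichment, the percentile of a gene's highest peak among genes with a shared peak was averaged over the replicates, and the median over a list was compared with 10000 random lists matched on the number of shared peaks (1, 2, 3, or 4 and more), two-sided. Genes of non-coding RNA were among those drawn, and no protein-coding background was run for the enrichment test. The p-values of each test were adjusted over 16 lists by the Benjamini-Hochberg method, with a threshold of 0.05. Tested on simulated data, the enrichment test called 2 of 100 lists of 30 genes with no shift at an unadjusted p under 0.05, 19 with a shift of 10 percentiles, 56 with 20 and 94 with 30. Fisher's test called 4 of 200 unchanged lists of 40 genes, and 200 of 200 after 20 members had lost their peak.

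That first set was a fold of at least 2 with an adjusted p under 0.01, the upper 50% of each list, overlap of at least 50% of both peaks, a peak in at least 1 list, the mean over a gene's peaks, no matching on the number of peaks, and leaving out each replicate in turn. Alternatives chosen after seeing the data were peaks spanning at most 1000 bp, genes spanning under 5000 bp, overlap with a peak of the same gene, a background of genes with a peak on a protein-coding transcript, matching on deciles of genomic span, and matching on deciles of a coverage proxy. The proxy of a gene is the size of the normal deviate of its peaks' deposited p-values divided by their log2 enrichment, since deeper coverage gives a smaller p at the same enrichment. The highest value over the gene's peaks was taken in each list. Peaks with a p-value listed as 0 (2305, 2685 and 2695 in the lists) were left out of it. It could not be had for 395 genes, which were left out of that matching. Gene ontology terms with 20 to 300 genes, likewise chosen after seeing the data, were compared with 100000 resamples. A test of the m6A sequence motif and of regions against random exonic positions needs the genome sequence or the exon annotation and was not made. The gene ontology terms were also the authors'. Their annotation texts beyond these terms, region, transcript type and gene were not used here.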

Results

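N6-methyladenosine (m6A), a methylated base of messenger RNA, was mapped in the anterior cingulate cortex of adult wild-type mice by antibody enrichment of RNA fragments followed by sequencing. Each of 3 independent pools of 10 mice gave an input library and an immunoprecipitated (IP) library, 6 libraries in all. The pools are called replicates 1, 2 and 3. The authors deposited a list of m6A peaks for each IP and input pair, with a log2 enrichment of IP over input and a p-value for each peak. All enrichments and peak p-values below are those of the authors' deposited tables. The tables hold no read counts, so the depth of each library is unknown. All coordinates are on the mouse assembly GRCm38, and all samples belong to a single genotype, tissue and condition.

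The first question was how widely m6A peaks were spread over the genes of this tissue. Dlg2, which encodes a postsynaptic scaffold protein, held 42 peaks found in all 3 replicates, the highest number of any gene. It was followed by Kcnq1ot1, an antisense non-coding RNA of the imprinted Kcnq1 locus, with 40, and by Kcnip4, whose product binds potassium channels, with 38. Adgrb3, a synaptic adhesion receptor, held 26 and the uncharacterised gene 9330162G02Rik held 25. These counts were not set against gene length and include intronic peaks, so they do not rank genes by degree of methylation. The highest shared peak of Dlg2 lay in an intron at log2 enrichments of 3.81 to 3.96, and that of Adgrb3 was annotated to coding exons at 4.20 to 4.59, with a genomic span of 275762 to 275937 bp over exons and introns. The highest shared peaks were at 4.11 to 4.99 in Kcnq1ot1, 2.28 to 2.57 in an intron of Kcnip4, and 3.37 to 3.67 in 9330162G02Rik. The lists held 55106, 55571 and 52554 peaks (mean 54410 ± 1624 SD, n = 3) in 16936, 17173 and 17047 genes (mean 17052). The median log2 enrichment was 1.54, 1.65 and 1.64 in replicates 1, 2 and 3. Of 18887 genes with a peak in any list, 15314 (81.1%) had a peak in all 3 lists and 14644 (77.5%) had a peak at an overlapping position in all 3. A gene with such a shared peak held a median of 2 of them.

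Cap1 and Ythdf1 are the genes that the series title names in connection with actin turnover and synaptic function. Cap1 (ENSMUSG00000028656) encodes a protein that binds actin monomers and promotes the recycling of cofilin-bound actin. Its gene lies on the minus strand of chromosome 4 from 122859047 to 122886056. The strongest Cap1 peak lay in the 3' UTR in all 3 replicates, starting at 122859047 and ending at 122859496 in replicate 1 and at 122859396 in the other two. Its log2 enrichment was 1.65, 2.05 and 1.53 (3.14-fold, 4.14-fold and 2.89-fold), at percentiles 55.0, 64.0 and 44.5 of all peaks in the lists. A weaker peak over the Cap1 stop codon had log2 enrichments of 1.19, 1.24 and 1.26, and another in the coding exons had 1.29, 1.22 and 1.09. A peak over the Cap1 start codon was listed in replicates 1 and 3, at 1.05 and 1.15, and not in replicate 2. Ythdf1 (ENSMUSG00000038848) encodes a cytoplasmic protein that binds m6A and promotes translation of the bound mRNA. Its gene lies on the minus strand of chromosome 2 from 180904377 to 180920949. The strongest Ythdf1 peak spanned 13870 to 13920 bp of genome, from 180905252 to 180919171 in replicate 1, and so most of the gene. It was annotated to the stop codon, with log2 enrichments of 3.08, 3.44 and 3.34 (8.48-fold, 10.8-fold and 10.1-fold) and p-values listed as 0. It stood at percentiles 86.4, 87.9 and 87.1 of all peaks. A peak in the Ythdf1 3' UTR had log2 enrichments of 0.93, 1.61 and 1.07. Among the 14644 genes with a shared peak, ranked by their highest peak, Cap1 stood at a mean percentile of 15.6 and Ythdf1 at 62.8.

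**Figure D1:**
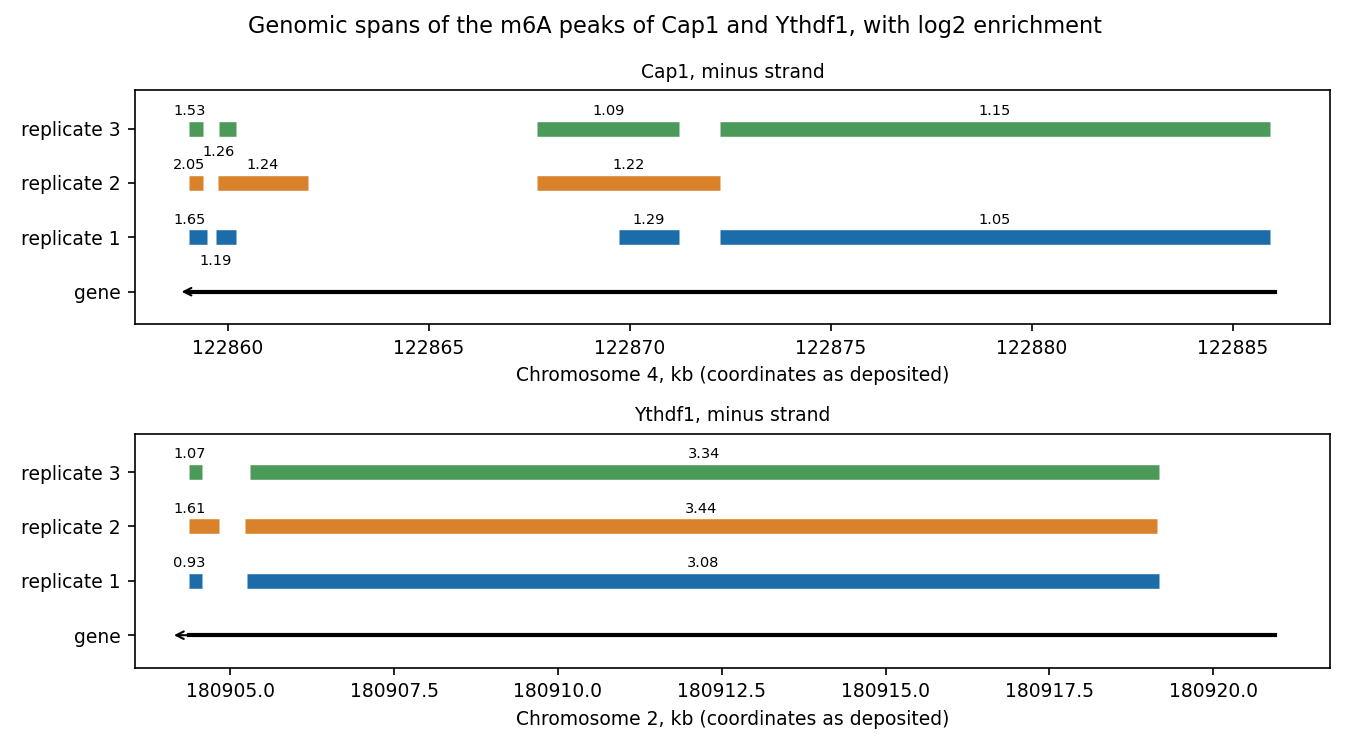
Peaks of Cap1 and Ythdf1 in the 3 replicates along GRCm38 coordinates, each bar a peak with its deposited log2 enrichment. The 3' UTR peak of Cap1 sits at 1.53 to 2.05 and the long peak of Ythdf1 annotated to the stop codon at 3.08 to 3.44.

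The next comparison asked how far the 3 pools held the same peaks. Peaks annotated to the stop codon, a region where m6A is known to be frequent, were the most often shared, with 93.1% ± 0.158 (SD, n = 3) overlapping a peak in both other lists. Start-codon peaks followed at 75.8% ± 2.06 and 3' UTR peaks at 68.3% ± 1.09. Intronic peaks were the least often shared at 41.4% ± 2.67. Over all regions, 35457, 35031 and 34583 peaks were shared by at least 1 bp on the same strand, or 64.4% ± 1.38 (SD, n = 3). After random placement of each peak of the other lists within its own gene, 22.9% ± 0.392 were shared, and 0 of 100 placements gave as high a count in any list. The placement covered introns, so calls confined to exons would exceed it whatever their cause. It does not argue against calls that recur at the same positions. In genes under 5000 bp, where introns matter less, the placed share was higher at 42.1, 41.0 and 41.8%, against 64.4, 61.6 and 62.9% observed, and again 0 of 100 placements came as high. The median log2 enrichment was 1.80, 1.93 and 1.91 for shared peaks and 1.24, 1.36 and 1.33 for the others. Peaks span introns in genomic coordinates, which eases overlap. When each list was limited to peaks of at most 1000 bp, so that a short peak had to overlap a short peak in both other lists, the shared percentage was 42.2, and with an overlap of at least 50% of both peaks it was 38.8.

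Enrichments at overlapping peaks were compared between each pair of replicates. The strongest peaks varied in some genes and not in others. The highest shared peak of Mir6363, a microRNA gene, ranged from 6.49 to 9.40 on the log2 scale, and that of Gprin2, which encodes a G protein-regulated neurite outgrowth protein, ranged from 5.85 to 8.91. Hras, which encodes a small GTPase of growth-factor signalling, stayed within 5.60 to 5.70. Across peaks, which are not independent replicates, Spearman's correlation of log2 enrichment was 0.841 between replicates 1 and 2, 0.847 between 1 and 3, and 0.847 between 2 and 3. The corresponding Pearson's correlations were 0.837, 0.844 and 0.841, over 36900, 36171 and 36329 pairs of peaks. Replicate 2 exceeded replicate 1 by a median log2 difference of 0.14, replicate 3 exceeded replicate 1 by 0.12, and replicate 3 differed from replicate 2 by -0.03.

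Where along the transcript the peaks lay was taken from the authors' annotation. The 3' UTR held 35.2% ± 0.665 (SD, n = 3) of the peaks and the stop codon 12.7% ± 0.450. Coding exons held 18.6% ± 0.523, introns 13.6% ± 0.569, exons of non-coding RNA 10.6% ± 0.122, the start codon 4.85% ± 0.234 and the 5' UTR 4.1% ± 0.294. Stop-codon peaks had median log2 enrichments of 2.64, 2.88 and 2.84 (6.22-fold, 7.34-fold and 7.15-fold), the highest of these regions in every replicate. Those of 3' UTR peaks were 1.37, 1.46 and 1.47, those of coding exons 1.39, 1.52 and 1.51, and those of introns 1.33, 1.39 and 1.34. Start-codon peaks had medians of 2.00, 2.17 and 2.09, 5' UTR peaks of 1.77, 1.89 and 1.82, and non-coding exons of 1.88, 2.05 and 2.04. Each of the 3 differences between the stop codon and the 3' UTR was larger than the range of either region over the replicates. Stop-codon peaks had longer genomic spans, with medians of 1638, 1750 and 1825 bp against 400 bp in the 3' UTR. Among peaks of at most 1000 bp, the stop-codon medians were 1.99, 2.09 and 2.03, those of the start codon 2.00, 2.08 and 2.01, and those of the 3' UTR 1.29, 1.36 and 1.37, so the stop codon no longer stood above the start codon in replicate 1. The stop codon held 6.47% of these short peaks, coding exons 11.4% and the start codon 2.09%. Of these short peaks, 84.7% ± 1.08 (SD, n = 3) at the stop codon, 64.0% ± 1.11 in the 3' UTR, 61.9% ± 5.56 at the start codon and 40.1% ± 2.78 in introns overlapped a peak of any span in both other lists. On average the start codon thus no longer stood above the 3' UTR, though it did in replicate 1. Among shared peaks the stop codon held 18.4%, the 3' UTR 37.3% and introns 8.73%. Peaks on protein-coding transcripts made up 82.2%, those on transcripts marked for nonsense-mediated decay 6.86%, antisense RNAs 3.60% and long intergenic non-coding RNAs 2.38%. No test was made against a chance level, since the exons of the annotation were not among the references used here.

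**Figure D2:**
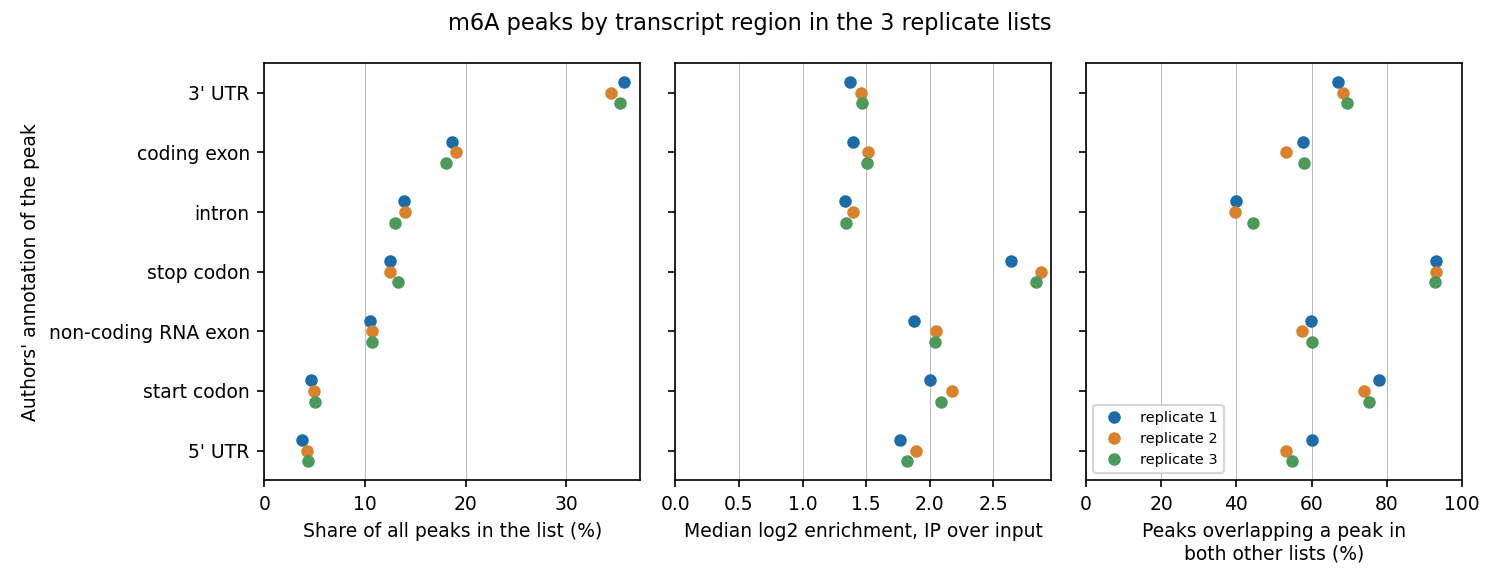
Share of each list in percent, median log2 enrichment, and percentage of peaks overlapping a peak in both other lists, by annotated region, with a dot for each replicate. Stop-codon peaks have the highest medians, 2.64 to 2.88, and 93.1% of them were shared on average.

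The genes with the strongest shared peaks, ranked by the lowest enrichment over the 3 lists, were a mixed set. First came Tfap2a, which encodes a transcription factor of neural crest and epithelial development, with a 3' UTR peak on chromosome 13 (40716452 to 40716726 in replicate 1) at log2 enrichments of 7.55 to 8.07. Gm13848, a long intergenic non-coding RNA on chromosome 6, followed at 7.46 to 8.32, and Gm884, with a coding-exon peak on chromosome 11, at 7.42 to 8.85. The next were Mir6363 on chromosome 16 (50727132 to 50727245 in replicate 1), the small nucleolar RNA Gm25857 at 6.24 to 9.19, Gm47113 at 6.12 to 8.82, and Lamb3, a laminin subunit, at 6.12 to 6.42. The overlapping Lamb3 peaks were unlike: a 5' UTR peak spanning 21687 bp in replicates 1 and 2, and an intronic peak of 548 bp in replicate 3. Of 9130230N09Rik the range was 5.98 to 8.94 and of Rps19bp1, whose product binds a ribosomal protein, 5.84 to 6.16. The lysophosphatidic acid receptor gene Lpar2 ranged from 5.80 to 7.88 and the prostaglandin F receptor gene Ptgfr from 5.72 to 8.40. Gm17484 lay at 5.69 to 5.85 and Sac3d1, linked to centrosomes, at 5.65 to 5.83 over the stop codon. Gprin2 and Hras completed the 15 genes. The Hras 3' UTR peak on chromosome 7 (141190580 to 141191579 in replicate 1) had p-values listed as 0. The largest deposited adjusted p over the lists was 0.00022 for Tfap2a, 0.000255 for Gm13848, 0.000344 for Lpar2 and 0.000318 for Ptgfr, whose peaks stood at median percentiles of 38.6 to 42.1 by the size of their p-value. Of these 15 genes, 9 had their peak on a protein-coding transcript or one marked for nonsense-mediated decay, 7 varied by more than 2 log2 units over the lists, and 5 by less than 0.5, Lamb3 with its unlike peaks among them. With an overlap of at least 50% of both peaks required, Gm884, 9130230N09Rik, Rps19bp1, Lpar2, Ptgfr and Sac3d1 had no shared peak. The ranking describes the deposited values and carries no test.

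Gene groups fixed in advance were then asked whether their members carried shared peaks. All 46 genes of the postsynaptic density and glutamate receptor group did, among them Nlgn1 and Nlgn3, which encode neuroligin adhesion proteins. So did all 44 genes of presynaptic release, among them Syt2 and Pclo, and all 48 regulators of chromatin and transcription. Ribosomal protein genes stood apart, with a shared peak in 33 of the 63 that had any peak, and Rpl8, Rpl17 and Rpl19 were among 12 of 75 with none. The share was compared by two-sided Fisher's exact test with that of all other genes carrying a peak in at least 1 list, and p was adjusted over 16 groups by the Benjamini-Hochberg method. Ribosomal protein genes had 52.4% against 77.7% of other genes (adjusted p 8.96e-05). The postsynaptic group had 100% against 77.5% (adjusted p 9.79e-05), with adjusted p 0.000114 for presynaptic release and 8.96e-05 for the chromatin group. Against genes with a peak on a protein-coding transcript alone, these 3 neuronal and chromatin groups had an adjusted p of 0.0105 each, and ribosomal proteins had 53.3% (adjusted p 4.54e-09). The gap was smaller against random genes matched on deciles of genomic span, where ribosomal proteins had 52.4% against 68.0% (adjusted resampling p 0.0422).

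Another 6 groups passed the threshold against all genes and no longer did so against genes with a protein-coding peak. Actin turnover, the process named in the series title, had a shared peak in 52 of 55 genes, or 94.5% (adjusted p 0.00329, and 0.248 with the protein-coding background). The exceptions were Gsn, Actg1 and Coro1a, which encode gelsolin, gamma-actin and a coronin, and were chosen for mention after their values were seen. The m6A writers, erasers and readers had one in all 26 genes with any peak (0.00487, then 0.109), while the readers Igf2bp1 and Igf2bp2 had no peak. Immediate early genes had one in 29 of 30 (0.0174, then 0.341), and stress and mood related genes in 32 of 34 (0.0425, then 0.448), with no peak in Slc6a4, the serotonin transporter gene. The 15 markers of excitatory neurons and the 15 of the oligodendrocyte lineage all had one (0.0495 each, then 0.392 each). No share above 15 of 15 was possible, and it gave an unadjusted Fisher's p of 0.245 with the protein-coding background. A pass on the higher side was thus out of reach there, and this failure says nothing about these markers. Without any one of the replicates, the stress, excitatory and oligodendrocyte groups missed the threshold, at adjusted p of 0.0771 to 0.225, 0.177 to 0.225 and 0.177 to 0.225. For the excitatory and oligodendrocyte groups, again at 15 of 15, this too was fixed in advance, with an unadjusted Fisher's p of 0.149 to 0.15. The m6A group missed it at 0.0583 without replicate 1 and 0.0703 without replicate 3, and immediate early genes at 0.151 without replicate 3.

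The other groups did not pass against all genes. GABAergic transmission had a shared peak in 26 of 28 genes (adjusted p 0.0966), glycolysis and housekeeping genes in 23 of 27 (0.521), astrocyte markers in 14 of 15 (0.247), microglia markers in 14 of 15 (0.247) and endothelial and mural markers in 13 of 15 (0.545). Genes of nuclear-encoded oxidative phosphorylation had one in 38 of 56, or 67.9% against 77.6% (0.142), with Ndufb9 and Cox8a holding no peak, and passed on the lower side with the protein-coding background (69.1%, adjusted p 0.00399) and without replicate 2 (72.7%, 0.0449). Glycolysis and housekeeping genes passed without replicate 2 (100%, 0.0449), and Ldhb and Tuba1b of that group had no peak. Counted as a peak in at least 1 list against all protein-coding genes, the share of ribosomal proteins turned above that of the background at 84.0% (adjusted p 0.000427), and that of oxidative phosphorylation at 96.6% (2.18e-08). That background holds genes not expressed in the tissue. Expression was not matched in any of these tests, since the tables hold none.

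The last comparison asked which groups held the strongest or weakest peaks, as the percentile of a gene's highest enrichment among the 14644 genes with a shared peak. Actin turnover genes had weak highest peaks: of 52 genes, 40 stood below the 50th percentile and 26 below the 25th. Among the lowest were Cdc42, a small GTPase that drives filopodia, at log2 enrichments of 0.81, 1.06 and 0.91, the Arp2/3 complex gene Arpc1a at 1.24, 1.16 and 1.05, and Cap2, the relative of Cap1, at 1.33, 1.27 and 1.20. These 3 were chosen after their values were seen. Members are named by the lowest enrichment of their best shared peak over the lists, which need not follow the percentile order. By this measure, high shared peaks were held by the WAVE complex gene Abi2 at 3.91 to 4.41, Srgap3, which acts on Rac1, at 3.63 to 3.83, and the cofilin phosphatase gene Ssh2 at 3.62 to 3.79. The group's median percentile was 23.9, against 52.5 for 10000 random lists matched on the number of shared peaks (95% range 40.7 to 64.4). The permutation p of 0.0002 is the smallest these lists allow, and the Benjamini-Hochberg adjusted p over 16 groups was 0.00107. All list tests of this kind were two-sided. The median lay below that of the random lists in each of the 3 replicates.

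Genes of translation and energy metabolism also had weak highest peaks. Of 33 ribosomal protein genes, 32 stood below the 50th percentile, among them Rpl39 at log2 enrichments of 2.07 to 2.35. Of 38 oxidative phosphorylation genes, 34 stood below the 50th percentile. High shared peaks were held by the complex I genes Ndufb2 at 3.69 to 4.39, Ndufs4 at 3.05 to 5.29 and Ndufa2 at 2.48 to 3.80. In glycolysis and housekeeping, 22 of 23 genes lay below, with the exception of the aldolase gene Aldoa, whose 5' UTR peak was at 3.36 to 4.30. Tuba1a, a tubulin, had 2.59 to 2.74 and Calm3, a calmodulin, 2.48 to 2.72. The median percentiles were 12.0 against 46.8 in random lists for ribosomal proteins, 12.6 against 46.6 for oxidative phosphorylation, and 15.1 against 49.2 for glycolysis and housekeeping. The adjusted permutation p was 0.00107, 0.00107 and 0.0016, the first and second from the smallest p the random lists allow, and each median lay below the random lists in all 3 replicates.

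The call for presynaptic release, as opposed to those above, did not hold under any alternative. This group had a median percentile of 40.9 against 55.7 in random lists (adjusted permutation p 0.0486), with 26 of 44 genes below the 50th percentile and its median lower in all 3 replicates. Within it the SNARE gene Snap25, chosen for mention after its values were seen, stood at log2 enrichments of 1.34, 1.26 and 1.29, while the calcium sensor gene Syt2 reached 4.46 to 4.80 and the active zone gene Pclo 4.15 to 4.81. Its adjusted p was 0.0827 to 0.111 without any one of the replicates and up to 0.359 under the other alternatives. Postsynaptic density and glutamate receptor genes had 36 of 46 at or above the 50th percentile, with Nlgn1 at 4.51 to 4.90 and Nlgn3 at 4.24 to 4.53. Their median of 62.0 was not told apart from the 56.2 of random lists (adjusted p 0.416). GABAergic transmission had 18 of 26 genes below the 50th percentile and a median of 35.5 against 53.4 (adjusted p 0.0722), and passed without replicate 1 at 32.5 (0.0192, range over its alternatives 0.0192 to 0.188). Members with high shared peaks included the GABA receptor genes Gabbr2 at 3.98 to 4.25 and Gabra5 at 3.47 to 3.78.

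**Figure D3:**
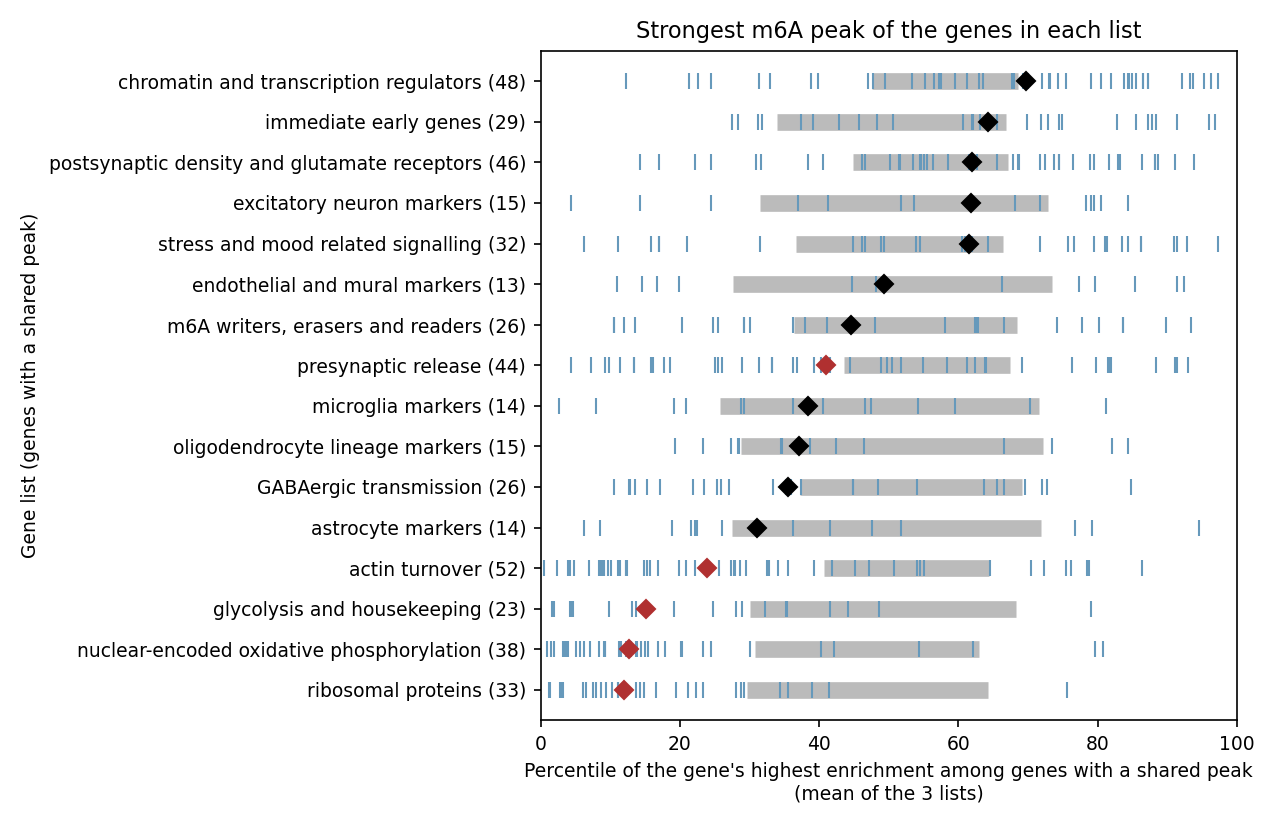
Percentile of the highest enrichment of each gene (ticks) in the 16 gene groups, with the group median (diamond, red where adjusted p was under 0.05) and the 95% range of medians of random lists matched on the number of shared peaks (grey bar). The medians of actin turnover (23.9), ribosomal proteins (12.0), oxidative phosphorylation (12.6), glycolysis and housekeeping (15.1) and presynaptic release (40.9) lie below their bars, as does that of GABAergic transmission (35.5), which did not pass the adjusted threshold.

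The groups of regulators and signalling genes did not pass the test of enrichment. Among chromatin and transcription regulators, 37 of 48 genes stood at or above the 50th percentile, with high shared peaks in the remodelling genes Arid1b at log2 enrichments of 4.87 to 5.12 and Arid1a at 4.61 to 5.42 and the transcription factor gene Zfhx3 at 4.82 to 6.10. The group's median was 69.8 against 58.0 in random lists (adjusted permutation p 0.0722). It passed without replicate 1 at 71.3 (0.0224), without replicate 2 at 71.1 (0.0218) and without matching on the number of peaks (0.00704), and its alternatives reached up to 0.403. Immediate early genes had 20 of 29 at or above the 50th percentile and a median of 64.3 against 50.6 (0.191), which passed with the mean over a gene's peaks at 68.4 (0.0294, range over its alternatives 0.0294 to 0.188). High shared peaks were held by Ier5 at 5.07 to 5.18, Ier2 at 4.76 to 5.03 and the neurotrophin gene Bdnf at 4.24 to 4.55, each over the stop codon. Stress and mood related genes had 20 of 32 at or above the 50th percentile and a median of 61.5 against 52.0 (0.359), with high shared peaks in the transcription factor gene Creb1 at 4.94 to 5.41, the serotonin receptor gene Htr2a at 4.45 to 4.72 and Ntrk2, which encodes the BDNF receptor, at 4.29 to 4.54. The m6A writers, erasers and readers had 14 of 26 below the 50th percentile and a median of 44.6 against 52.8 (0.416), with high shared peaks in Rbm15 at 4.43 to 4.75 and Wtap at 4.07 to 4.56 of the writer complex and the reader gene Ythdc1 at 3.88 to 4.14.

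No group of cell type markers passed the test of enrichment. Excitatory neuron markers had 10 of 15 genes at or above the 50th percentile and a median of 61.9 against 52.8 (adjusted permutation p 0.452), with high shared peaks in the transcription factor genes Bcl11b at log2 enrichments of 3.84 to 4.34, Foxp2 at 3.80 to 3.88 and Neurod2 at 3.78 to 3.84. Astrocyte markers had 10 of 14 below and a median of 31.1 against 49.8 (0.191), with high shared peaks in Sox9 at 4.34 to 5.02, the water channel gene Aqp4 at 3.80 to 3.87 and the glutamate transporter gene Slc1a2 at 3.66 to 3.84. Oligodendrocyte lineage markers had 11 of 15 below and a median of 37.1 against 50.9 (0.371), with high shared peaks in Cspg4 at 3.76 to 4.01, Ugt8a at 3.55 to 3.69 and Pdgfra at 3.45 to 4.24. Microglia markers had 10 of 14 below and a median of 38.4 against 48.4 (0.452), with high shared peaks in Tmem119 at 3.81 to 4.02, Sall1 at 3.32 to 3.77 and Cx3cr1 at 3.04 to 3.34. Endothelial and mural markers had 7 of 13 below and a median of 49.3 against 50.7 (0.912), with high shared peaks in Kdr at 4.39 to 4.68, Cldn5 at 4.23 to 4.72 and Slc2a1 at 4.03 to 4.15. These groups hold 13 to 15 genes each, and a difference that failed the test is not shown to be absent. Over all 16 groups, 5 passed an adjusted p of 0.05 on the lower side, presynaptic release among them, and 0 on the higher side. The chromatin group, whose median lay above the 95% range of its random lists (upper limit 68.6), passed on the higher side in 4 of 6 alternatives, while presynaptic release passed on the lower side in 0 of 6. Among the 4 was the setting without matching on the number of peaks. The chromatin group did not pass without replicate 3 (adjusted permutation p 0.0621) or with the mean over a gene's peaks (40.9 against 36.0, 0.403).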

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

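Among the tests in this part, the position of the strongest peaks by p-value, the coverage matching of gene lists, and the test of a difference between a pair of lists were chosen only after the result was seen. No test for a sample far from the others was made, since the groups hold 3 samples each.

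Each list held 10 peaks on the mitochondrial genome, which counted in the totals above but in no comparison of their own. Of the 30 peaks, 26 were found in all lists. The 30 had log2 enrichments of 0.82 to 2.19, and the strongest was in mt-Nd2 (named beyond the rule) at 2.13, 2.19 and 2.15. A further 134 peaks per list on average (SD 11.8; 147, 124 and 131) had no gene in the authors' annotation and so entered no comparison of genes, with median log2 enrichments of 1.75, 2.03 and 1.71, and 88, 70 and 76 of them were found in all lists.

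Some of the strongest shared peaks differed widely between replicates, as 7 of the 15 named genes, Mir6363 and Gprin2 among them, ranged over more than 2 log2 units. Low input coverage, which inflates a ratio, was weighed as a technical explanation. Over 30399 sets of peaks, the median SD of log2 enrichment in the top decile was 1.12 times that of the fifth and sixth deciles (0.26 against 0.24, bootstrap 95% range 1.06 to 1.19), above the bound of 1 that would have argued against this explanation and below the 1.5 set for it. Below the top decile the spread did not rise throughout. The median SD went from 0.122 in decile 1 up to 0.241 in decile 6 and down to 0.199 in decile 9. The named strongest peaks stood at a median percentile of 47.6 by the size of their p-value, against 82.4 for the top decile as a whole, so weak coverage may account for part of the named set. Coverage itself was not measured, the first of these tests did not decide, and no biological explanation was tested.

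Introns held 13.6% of the peaks although poly(A) RNA was selected, and 41.4% of these were found in all lists, against 68.3% of 3' UTR peaks. Calls made from noise in weakly covered introns were weighed as a technical explanation. Against 3' UTR peaks of like enrichment and p-value, the share differed by -2.54 percentage points on average (SD 3.17, n = 3; -4.63, -4.10 and 1.10 in the lists). It also exceeded the 14.4% reached after random placement within the gene, where 0 of 100 placements came as high in any list. The placement argues against calls scattered at random over the gene, but not against calls that recur at the same positions. The matched 3' UTR peaks were shared at 43.9%, less often than 3' UTR peaks as a whole, and may hold noise to a like degree. Noise as a cause is thus not decided by these values. Unspliced RNA and retained introns stay open and untested, and no biological explanation was tested.

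Actin turnover, ribosomal protein, oxidative phosphorylation and glycolysis genes had weak highest peaks under all 6 alternatives, while presynaptic release passed with the reported setting alone and under none of its 6 alternatives (adjusted p 0.0827 to 0.359). A technical explanation is that deeply covered transcripts have lower enrichments whatever their group. With matching on the coverage proxy, which left out members without a proxy (48 of 52 actin turnover and 19 of 23 glycolysis genes remained), 4 of the 5 lists stayed past the threshold and presynaptic release did not (median 40.9 as before, adjusted p 0.359 in place of 0.0486), since the median of its random lists moved from 55.7 to 46.7. Actin turnover and postsynaptic genes had similar proxy percentiles (85.4 and 89.5). Their median enrichment percentiles of 23.9 and 62.0 differed by -38.1 (permutation p 1e-05, the smallest the resamples allow, and adjusted p 1.5e-05 over 3 comparisons). This pair was chosen for its differing medians and was not matched on the number of peaks. The adjustment did not cover the other pairs of lists, so these p-values overstate the evidence. The proxy is computed from the enrichment itself, so similar proxy percentiles do not show similar coverage. Whether coverage is a cause in actin turnover is thus not decided. Ribosomal proteins and oxidative phosphorylation stood at 46.4 and 57.5 by the proxy, so it does not track transcript abundance alone, an effect of abundance on these lists may remain, and no biological explanation was tested.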

How the results depend on the processing

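The limit on genomic span, the limit to short genes, overlap within the same gene, the protein-coding background, the matching on span and the matching on the coverage proxy were alternatives chosen only after seeing the data. No paired analysis was possible because the tables hold only comparisons of IP with input and no values per library.

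The enrichment calls for actin turnover, ribosomal proteins, oxidative phosphorylation, and glycolysis and housekeeping kept their direction and their side of the threshold under all 6 alternatives run (adjusted p up to 0.0016, 0.00107, 0.00107 and 0.0064). The share calls for the postsynaptic, presynaptic and chromatin lists did so under all 7 alternatives (adjusted p up to 0.0256, 0.0224 and 0.0336). The number of genes with a peak per replicate moved by less than 1.5 times under the alternatives run for it (the stricter threshold, the upper 50% and leaving out each replicate). Of 343 values of 70 named genes, 299 moved by less than 1 SD, and under overlap of at least 50% of both peaks 7 genes (Gm884, 9130230N09Rik, Rps19bp1, Lpar2, Ptgfr, Sac3d1 and Sox9) had no shared peak. The stricter threshold could not move any named gene, since every named peak already passed it. Leaving out a replicate that does not hold the lowest value can also leave that value unchanged. The count of 299 is thus partly fixed in advance. Where no reason is given below, the cause was not tested.

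The upper 50% of each list by enrichment held 27205 peaks per replicate by construction, and on average 17750 of them overlapped a peak in the upper 50% of both other lists. Shared peaks numbered 21121 (38.8%) with overlap of at least 50%, 14864 (42.2%) with every list limited to spans of at most 1000 bp, and 3290 (62.9%) in genes under 5000 bp, where fewer peaks were left. Between any 2 replicates the shared percentage was 73.4 to 74.0, since fewer lists have to hold the peak. Mean Spearman's correlation of 0.845 moved to 0.873 with overlap of at least 50%, 0.861 at the stricter threshold, and 0.841 to 0.847 without a replicate.

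At the stricter threshold the 3' UTR held 34.5% of peaks, introns 10.5%, the stop codon 15.5%, the start codon 5.69% and the 5' UTR 4.39%. Among peaks spanning at most 1000 bp these were 43.5% in the 3' UTR, 11.4% in coding exons, 20.2% in introns, 6.47% at the stop codon, 12.2% in non-coding exons, 2.09% at the start codon and 3.65% in the 5' UTR, since spans differ between regions. Among peaks shared by any 2 replicates the ranges were 36.5 to 37.4% in the 3' UTR, 16.7 to 17.0% in coding exons, 9.95 to 10.7% in introns, 16.2 to 16.6% over the stop codon, 9.96 to 10.1% in non-coding exons, 5.32 to 5.61% over the start codon and 3.66 to 3.97% in the 5' UTR.

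In place of 10 lists, 16 passed the share test with a peak in at least 1 replicate against all protein-coding genes, 5 with the protein-coding background, 6 with matching on span, and 5 to 9 without a replicate. With a peak in at least 1 replicate, a background holding genes not expressed in the tissue, ribosomal proteins (84.0%, adjusted p 0.000427) and oxidative phosphorylation (96.6%, 2.18e-08) turned above other genes. There GABAergic, astrocyte, microglia and endothelial lists passed at 100% each, and glycolysis and housekeeping at 93.1%. Actin turnover no longer passed at the stricter threshold (87.3%, 0.0907), with the protein-coding background (94.5%, 0.248) or with matching on span (94.5%, 0.104). The m6A list no longer passed with the protein-coding background (100%, 0.109) or without replicate 1 or 3 (100% in each, 0.0449 to 0.0703 over the 3), nor did immediate early genes with that background (96.7%, 0.341) or without replicate 3 (96.7 to 100% over the 3). Stress and mood genes did not pass at the stricter threshold (88.2%, 0.159), with the protein-coding background (94.1%, 0.448), with matching on span (94.1%, 0.323) or without a replicate (94.1 to 97.1%). Excitatory and oligodendrocyte lists, at 100% throughout, did not pass in these settings either (adjusted p 0.0528 to 0.392). Except at the stricter threshold, a full list of 15 could not pass. Its unadjusted Fisher's or resampling p was 0.0832 or more in the other settings. Oxidative phosphorylation passed below other genes at the stricter threshold (59.6%, 0.0225), with the protein-coding background (69.1%, 0.00399) and without replicate 2 (72.7 to 77.8% over the 3), and glycolysis and housekeeping passed without replicate 2 (85.2 to 100% over the 3). Ranges of the adjusted p over the 7 alternatives were 7.74e-10 to 0.248 for actin turnover, 0.0016 to 0.109 for m6A, 7.02e-06 to 0.341 for immediate early genes, 1.72e-05 to 0.448 for stress genes, 2.18e-08 to 0.323 for oxidative phosphorylation and 0.00106 to 1 for glycolysis.

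In the enrichment test, presynaptic release no longer passed with the mean over peaks (30.8, 0.139), without matching (40.9, 0.277), with the coverage proxy (40.9, 0.359) or without a replicate (42.5 to 43.0, adjusted p 0.0827 to 0.111). GABAergic transmission passed with the mean over peaks (26.6, 0.04) and without replicate 1 (32.5 to 37.9 over the 3, 0.0192 to 0.111), and immediate early genes with the mean over peaks (68.4, 0.0294). Chromatin regulators passed without matching (69.8, 0.00704), with the coverage proxy (69.8, 0.0122) and without replicate 1 or 2 (69.9 to 71.3 over the 3, 0.0218 to 0.0621), and with the mean over peaks reached 0.403.

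Settings named in advance that could not be run for want of exon annotation, genome sequence or values per library were placement within exons, every region a peak touches, a stop-codon window of another width, the motif settings, matching on exonic length, and all settings of IP against input expression. Depth is unknown, so what it limits was not assessed.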

Other observations

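In this part, the gene ontology terms and the differences between pairs of lists were tests chosen only after the result was seen.

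Among 853 gene ontology terms of 20 to 300 genes, 173 had a lower and 38 a higher mean percentile of a gene's highest peak than genes with the same number of shared peaks, at a Benjamini-Hochberg adjusted permutation p under 0.05. With matching on the coverage proxy as well, 90 of the lower and 35 of the higher terms also passed. Terms are nested and share genes. The resamples drew from genes with a shared peak, those of non-coding RNA included. Peaks on long intergenic and antisense RNAs had higher median log2 enrichments (2.18 and 1.98 on average) than those on protein-coding transcripts (1.57). Whether this background moved terms to the lower side was not tested. The highest by mean percentile were acetylgalactosaminyltransferase activity (mean percentile 75.3, 22 genes, adjusted p 0.000753), acetylglucosaminyltransferase activity (74.8, 25 genes, adjusted p 0.000322), adenylate cyclase-activating G protein-coupled receptor signalling (73.7, 37 genes, adjusted p 0.000322), sulfotransferase activity (72.0, 33 genes, adjusted p 0.000322) and positive regulation of synapse assembly (70.6, 40 genes, adjusted p 0.000569). The lowest were the tricarboxylic acid cycle (19.3, 24 genes), the membrane coat (21.2, 24 genes), the myelin sheath (21.6, 113 genes), the cytosolic large ribosomal subunit (22.3, 21 genes) and the U2-type catalytic step 2 spliceosome (24.0, 23 genes), each with an adjusted p of 0.000322.

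The fixed list of presynaptic release stood below that of the postsynaptic density and glutamate receptors, with medians of 40.9 and 62.0 that differed by -21.1 percentiles (adjusted permutation p 0.00079 over 3 comparisons chosen for their differing medians, not matched on the number of peaks). The adjustment did not cover the other pairs of lists from which these were picked, so this p overstates the evidence. Ontology terms of the synapse went in different directions, and no difference between terms was tested. Their values are on another scale than the list medians, which rank a gene among all genes with a shared peak. Term means rank a gene among those with the same number of shared peaks. The terms postsynapse (mean percentile 29.3, 73 genes, adjusted p 0.000322, and 0.000554 with the coverage proxy), postsynaptic density (44.0, 161 genes, 0.0363, then 0.611), dendritic spine (42.0, 83 genes, 0.0461, then 0.288), synaptic vesicle (38.7, 101 genes, 0.000753, then 0.169) and integral component of the synaptic vesicle membrane (31.4, 24 genes, 0.00973, then 0.139) were lower, and integral component of the postsynaptic density membrane (65.7, 35 genes, 0.00893, then 0.0307) was higher.

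A hypothesis tested here was that the m6A antibody also recognises m6Am, the dimethylated adenosine next to the mRNA cap, which would raise 5' UTR peaks that begin at the annotated 5' end of the gene. These made up 14.4% of 5' UTR peaks, and their median log2 enrichment exceeded that of the other 5' UTR peaks by 0.46 on average (0.44, 0.39 and 0.56 in the lists; 2.15 against 1.71, 2.22 against 1.83 and 2.30 against 1.74). The permutation p was 1e-05 in each list, the smallest the resamples allow. A contribution of m6Am is consistent with this difference. Yet 3' UTR peaks that reach the annotated 3' end also exceeded the other 3' UTR peaks, by 0.27 on average (0.26, 0.27 and 0.29), so an effect common to transcript ends may account for at least part of it. The tables hold no base positions of methylation to tell these apart.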
